A study of Mus musculus with 6 samples.

How the data were processed

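RNA sequencing measured gene expression in 6 libraries from mouse embryonic fibroblasts transformed with E1A and HrasG12V. The fibroblasts came as 3 lines. Each line gave a library from cells with a non-targeting guide RNA (sgNTC, p53 wild-type per the labels) and a library from cells with a guide RNA against the p53 gene (sgp53). The labels call the sgp53 cells of lines 1 and 3 p53 null and those of line 2 functionally inactive for p53. Cells recovered for 24 h at 37 °C in 5% oxygen before harvest, RNA samples had an integrity number above 8.0, and libraries were made from 1 µg of total RNA with a stranded TruSeq kit, all per the labels' protocols.

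The deposited table held raw read counts per gene symbol, with 1 column per library. The submitters' processing notes name CASAVA 1.8, STAR, DESeq2 and the mouse build mm10, without saying which made the counts. The read counter, its annotation and its strand setting are not given in the sources used here, so reads from overlapping genes on opposite strands, and from near-identical copies, cannot be told apart. The authors' counts had no normalization: the library totals differed, from 27503577 counts for sgNTC line 2 to 35860866 for sgp53 line 2. The table had 23420 genes, of which 5885 had no count in any library. It had 0 unassigned rows and 0 columns of unknown samples. A spreadsheet had turned 27 gene names into dates; 19 of these were tested, 2 passed the threshold, and none is named. No pair of libraries within a group agreed within sampling noise: the chi-square statistic per degree of freedom lay between 22.9 and 61.2, so each library counted as 1 replicate.

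From the counts, differences between sgp53 and sgNTC were tested in R 4.3.3 with the quasi-likelihood F-test of edgeR 4.0.16. Libraries were normalized by TMM, genes of low count were removed by filterByExpr on the 2 groups, and 13044 genes were tested. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 values of sgp53 over sgNTC, and each SE was the size of the fitted coefficient divided by the square root of F. Levels are CPM, counts scaled to the normalized library total, given as mean ± SD over the 3 libraries of a group. Differences within a line are between log2 CPM values with a prior count of 2. The fit had 4 residual degrees of freedom. The p-values measure the spread between the 3 lines of each group; the labels do not say whether the lines came from separate embryos. The sample descriptions give lines 2 and 3 a shared number that line 1 does not have, without saying what it marks, so the 3 lines may not be equally independent. With 3 libraries against 3, an exact permutation test of a single gene cannot go below 0.1, so single genes rest on the spread that edgeR shares across genes.

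The line numbers pair the libraries, because the labels give both libraries of a number to the same cell line. Their deviations from the group means correlated across genes at 0.089 for line 1, 0.0018 for line 2 and -0.027 for line 3. The fit with the line as a block, which has 2 residual degrees of freedom, was the alternative to the unblocked fit, and its value stands beside a result where it changes the call or moves a count of calls by over 1.5 times.

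The 34 gene lists were written from textbook knowledge before the data were examined, as were the tests, most of the alternatives and the rule for naming genes. Older symbols were looked up for 3 list members (Pidd1 as Lrdd, Tigar as 9630033F20Rik and Msmo1 as Sc4mol). The 30 lists with 3 or more tested genes were tested with camera (limma 3.58.1), two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over those lists. Camera with an estimated correlation and the rotation test fry were alternatives. Counts of called list members are over all genes tested and again adjusted over the list alone. The union of the 5 lists of p53 targets was also set, within each line, against 10000 random lists matched on mean expression in 20 bins.

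The named genes are Trp53, Cdkn1a, Mdm2 and Ccng1; in each direction, the 6 genes of largest fold change among those called, with the same sign in every line and a mean of at least 1 CPM; in each direction, 4 more by the same rule in the blocked fit, since it moved the count of calls by over 1.5 times; for each list, up to 3 called members of smallest adjusted p, or, where none was called, up to 2 of highest mean CPM; and the 4 genes of smallest p between lines with the members of the list on the sex of the lines. Genes named outside this rule are said to be so. For 2 genes that the rule takes, values are not reported here. Coordinates are of RefSeq genes on GRCm38.p6, the assembly that mm10 denotes.

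On simulated counts for the comparison of sgp53 with sgNTC, drawn for 13044 genes with 200 genes changed, edgeR recovered 22% of the genes changed 1.5-fold, 68% of those changed 2-fold, 82% of those changed 4-fold and 96% of those changed 8-fold, and 10 of its 144 calls were false. The blocked fit recovered 16%, 64%, 80% and 96%, and 14 of its 142 calls were false. No difference between lines was simulated, so this cannot show which of the 2 fits suits the data better. DESeq2 1.42.0 recovered 40%, 72%, 84% and 98%, and 66 of its 213 calls were false. Camera called a simulated list of 20 genes raised 2-fold and 0 of 30 unchanged lists. The simulated genes were drawn independently, so this does not show how camera with the preset correlation behaves on lists of correlated genes.

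The alternatives were RLE and upper quartile factors, no filter other than 1 count, a filter of at least 1 CPM in at least 3 libraries, DESeq2, limma-voom, the line as a block in edgeR and in DESeq2, the block with line 2 left out, and each library and each line left out. Added after seeing the data were a fit without Rn45s and a fit without sgNTC line 1 and sgp53 line 3. Intervals of ratios of low counts are exact binomial intervals at 95% and cover counting error only. The 10 symbols of the list of mitochondrially encoded genes did not match a name in the table, so that list gave no value.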

Results

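Gene expression was measured by RNA sequencing in E1A;HrasG12V mouse embryonic fibroblasts, which carry an adenoviral oncogene and an activated Ras gene, grown at 5% oxygen. Each of 3 lines was measured with a non-targeting guide (sgNTC, p53 wild-type) and with a guide against p53 (sgp53), which gave 6 libraries, 3 per group. Library totals were 32536641, 27503577 and 28956001 counts for sgNTC lines 1, 2 and 3, and 29703837, 35860866 and 29564516 counts for the sgp53 libraries of the same lines. The design asked how gene expression differs between p53 wild-type and p53-null cells at this oxygen level; the sgp53 cells of line 2 are labelled functionally inactive for p53 instead of null.

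The targeted gene, Trp53 (chromosome 11, 69580348 to 69591873), was lower in the sgp53 library of every line. Its level was 206, 277 and 253 CPM in sgNTC lines 1, 2 and 3 and 71.1, 72.0 and 113 CPM in the sgp53 libraries. The group means were 245 ± 35.9 and 85.3 ± 23.9 CPM (SD, n = 3 each), a log2 fold change of -1.52 (SE 0.21, edgeR adjusted p = 0.0168). This is RNA: it shows no protein level, and a frameshift need not lower it. The call was lost without sgNTC line 3 (edgeR adjusted p = 0.0721), without sgp53 line 1 (0.0679) and without sgp53 line 2 (0.0507). It was also lost without line 1 (0.0964), line 2 (0.112) or line 3 (0.0731), and in the blocked fit without line 2 (0.0955). The call was kept in 13 of all 20 alternatives, over which the adjusted p ranged from 1.68e-18 to 0.112.

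RNAs of well-known p53 targets fell with Trp53. Cdkn1a (chromosome 17, 29090979 to 29100722), which encodes the cyclin-dependent kinase inhibitor p21, fell from 697 ± 44.1 to 86.3 ± 13.6 CPM, a log2 fold change of -3.01 (SE 0.13, edgeR adjusted p = 0.000509). Mdm2 (chromosome 10, 117688875 to 117710758), the ubiquitin ligase that degrades p53, fell from 901 ± 146 to 136 ± 11.9 CPM (log2 fold change -2.73, SE 0.13). Ccng1 (chromosome 11, 40748552 to 40755309), cyclin G1, fell from 805 ± 191 to 72.6 ± 7.51 CPM (log2 fold change -3.47, SE 0.20). Of 64 tested targets in the union of the 5 p53 lists, 45 were lower, 0 were higher and 53 were lower when adjusted over the list alone. The count of lower targets was 27 without sgNTC line 3 and 25 without sgp53 line 1.

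**Figure D1:**
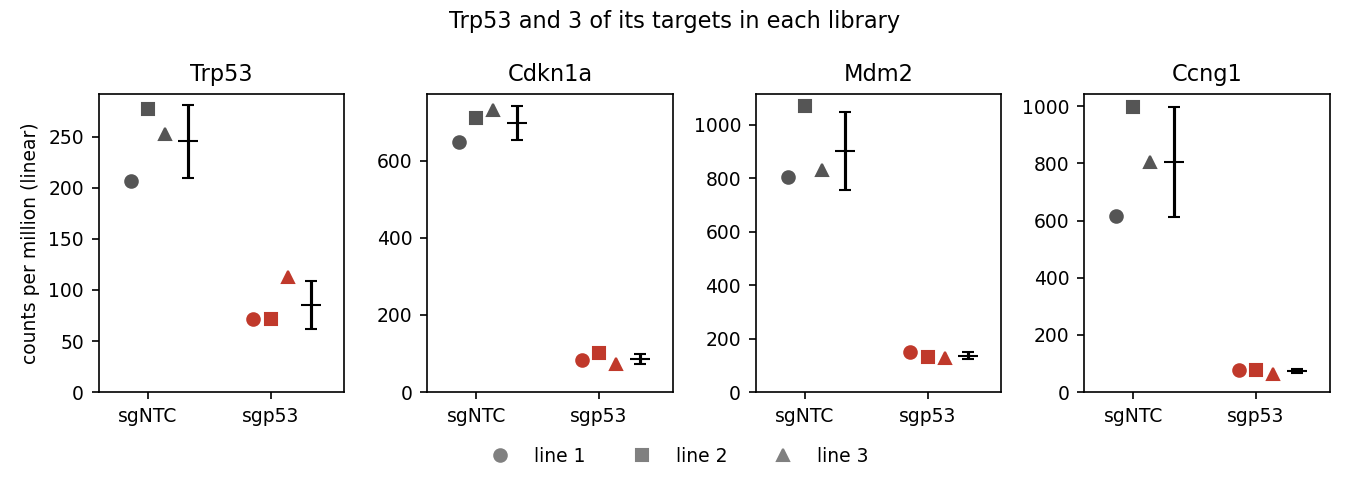
CPM (linear axis) of Trp53, Cdkn1a, Mdm2 and Ccng1 in each library, with circles, squares and triangles for lines 1, 2 and 3, and the mean with SD as a bar beside each group of 3. For all 4 genes the 3 sgp53 libraries lie below the 3 sgNTC libraries; Cdkn1a falls from a mean of 697 to 86.3 CPM.

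Called targets were lower in each functional class. Of the cell cycle arrest and feedback targets, 10 of 14 tested were lower (12 adjusted over the list alone), with a median log2 fold change of -2.10. The camera call was lost with an estimated correlation (adjusted p = 0.0521 with an estimated correlation). Of the apoptosis targets, 14 of 15 were lower (15 adjusted over the list alone). Eda2r, of the TNF receptor family, fell from 126 ± 20.4 to 2.84 ± 1.19 CPM. In the same list, Trp53inp1 fell from 123 ± 14.7 to 5.24 ± 1.99 CPM and Lrdd, the PIDD1 gene, from 55.4 ± 2.22 to 11.1 ± 1.45 CPM. Of the metabolism and redox targets, 9 of 16 were lower (10 adjusted over the list alone). They included adenylate kinase Ak1 (188 ± 23.0 to 16.6 ± 4.48 CPM), the epoxide hydrolase Ephx1 (32.7 ± 3.06 to 5.66 ± 0.971 CPM) and the reductase Dcxr (23.7 ± 1.70 to 3.69 ± 0.890 CPM). Among the other targets 12 of 17 were lower (16 adjusted over the list alone). They included Psrc1 (175 ± 25.1 to 13.0 ± 1.84 CPM), the phosphatase Ptp4a3 (83.7 ± 11.6 to 10.3 ± 0.753 CPM) and Abhd4 (108 ± 13.9 to 35.7 ± 2.74 CPM). Of the 8 DNA repair and nucleotide supply targets, 4 were lower (4 adjusted over the list alone). These included the nuclease Ercc5 (71.2 ± 11.0 to 24.3 ± 0.838 CPM), the polymerase Polk (96.4 ± 15.6 to 33.2 ± 3.77 CPM) and the replication clamp Pcna (256 ± 18.1 to 193 ± 13.4 CPM). This list's median was -0.33 and its camera call was lost (adjusted p = 0.222 with an estimated correlation). The calls of the apoptosis, metabolism and other lists held, each at an adjusted p of 0.0445 with an estimated correlation.

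Across all 13044 tested genes, 841 were called, 360 higher and 481 lower in sgp53, of which 132 and 190 changed over 2-fold. All 841 had the same sign in the 3 lines. That adds no support, since the groups did not overlap in any of the 841, which fixes the sign in each line. Over all tested genes the groups did not overlap in 4800 (36.8%), against 10% by chance. With the line as a block edgeR called 311 genes, 126 higher and 185 lower, of which 273 were also called without the block. Leaving out sgNTC line 1, 2 or 3 gave 700, 293 and 133 calls, and leaving out sgp53 line 1, 2 or 3 gave 146, 374 and 342. DESeq2 called 2382 genes, of which 840 were among the 841.

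The genes with the largest falls were led by Robo3, an axon guidance receptor, which had 190 counts in the sgNTC libraries and 1 count in the sgp53 libraries, a ratio of 203 (95% exact interval 36.02 to 8063). Ano3 (chromosome 2, 110655201 to 110950391), of the anoctamin family, fell from 52.7 ± 3.96 to 0.394 ± 0.339 CPM (log2 fold change -7.07, SE 0.43, edgeR adjusted p = 0.00146). Cd80 (chromosome 16, 38457430 to 38495958), a ligand that costimulates T cells, fell from 20.3 ± 9.74 to 0.282 ± 0.294 CPM (log2 fold change -6.20, SE 0.80, edgeR adjusted p = 0.0138). The gene listed as 9030617O03Rik, now named Dglucy, fell from 64.3 ± 20.5 to 1.41 ± 0.616 CPM, and 1700007K13Rik, which overlaps Mrps2, from 2.40 ± 0.642 to 0.0509 ± 0.0282 CPM. The blocked fit added Ddit4l, an inhibitor of mTOR signalling (20.04 ± 2.38 to 0.555 ± 0.00772 CPM), Fam212b (41.8 ± 5.87 to 1.36 ± 0.505 CPM) and the membrane protease St14 (71.6 ± 25.2 to 4.02 ± 2.31 CPM), which were lower in both fits.

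Of 23 tested extracellular matrix genes, 10 were higher in sgp53 and 0 lower (19 higher adjusted over the list alone), and the median log2 fold change was 2.79. The camera call of the matrix list was lost with an estimated correlation (adjusted p = 0.132 with an estimated correlation). DESeq2 called 16 of the 23 genes and limma-voom 6. Col1a1 (chromosome 11, 94936224 to 94953042), a chain of type I collagen, rose from 8.90 ± 3.72 to 459 ± 265 CPM (log2 fold change 5.68, SE 0.58, edgeR adjusted p = 0.00728), and Col1a2, its partner chain, rose from 11.0 ± 6.46 to 395 ± 340 CPM. The collagen crosslinking enzyme Lox rose from 3.77 ± 1.94 to 154 ± 69.4 CPM, the proteoglycan Bgn from 3.21 ± 3.24 to 223 ± 226 CPM, and Postn, periostin, from 0.552 ± 0.532 to 25.4 ± 16.6 CPM. Col5a1 rose from 175 ± 18.2 to 402 ± 23.3 CPM and Fbn1, fibrillin, from 135 ± 17.5 to 335 ± 24.1 CPM. Within lines 1, 2 and 3 the list's median log2 difference was 1.72, 1.43 and 3.92, and without line 3 the median fold change was 1.54. The sgp53 library of line 3 also had 3338 CPM of Rn45s, the ribosomal RNA precursor, against 636 to 864 CPM in the other libraries (Rn45s was chosen after its values were seen).

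Of the other genes with the largest rises, Igfbp5, which binds insulin-like growth factors, had 3 counts in the sgNTC libraries and 547 in the sgp53 libraries, a ratio of 171 (95% exact interval 58.1 to 830). All 3 and 386 of the 547 were in line 3, and the Igfbp5 call (edgeR adjusted p = 0.0313) was lost without any 1 library other than sgp53 line 3 (0.0581 to 0.119; 5.49e-12 to 0.131 over all alternatives). Cthrc1, a secreted protein of the matrix, rose from 0.0665 ± 0.0903 to 3.32 ± 3.16 CPM and Crabp1, which binds retinoic acid, from 3.47 ± 3.21 to 111 ± 105 CPM. Esm1 and Cdh13 were called by edgeR with the block and not without it (edgeR adjusted p = 0.0212 and 0.0152, against 0.125 and 0.119 without the block). Esm1 reached 140 CPM in sgp53 line 3 and was between 0.0362 and 1.00 CPM in the other 5 libraries.

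Some cytoskeletal and adhesion genes were higher in sgp53. Of 21 actin cytoskeleton and contractility genes, 10 were higher (15 adjusted over the list alone, and 4 over all genes in the blocked fit). They included the calponins Cnn1 (0.657 ± 0.273 to 11.5 ± 4.04 CPM) and Cnn2 (109 ± 17.0 to 304 ± 74.8 CPM, blocked edgeR adjusted p = 0.0613) and the focal adhesion protein Zyx (359 ± 15.6 to 493 ± 23.4 CPM). The camera call of this list was lost with an estimated correlation (adjusted p = 0.0505 with an estimated correlation). Of 17 integrin and focal adhesion genes, 4 were higher (6 higher and 2 lower adjusted over the list alone). They included the collagen receptor subunit Itga11 (0.141 ± 0.0594 to 2.91 ± 0.910 CPM), the kinase-like adaptor Ilk (132 ± 3.47 to 177 ± 5.41 CPM) and Itgb5 (134 ± 9.25 to 192 ± 10.8 CPM, blocked edgeR adjusted p = 0.0595). The list passed camera (adjusted p = 0.00142) and missed it with an estimated correlation (0.303). Among 15 TGF-beta and BMP response genes, 5 were higher and Tgfb1 was lower (10 and 1 adjusted over the list alone, and 2 and 0 over all genes in the blocked fit). This list passed camera (adjusted p = 1.19e-06) and missed it with an estimated correlation (0.17). The inhibitory Smad6 rose from 0.816 ± 0.576 to 8.63 ± 2.70 CPM and Pmepa1 from 51.5 ± 3.12 to 84.9 ± 13.6 CPM (blocked edgeR adjusted p = 0.0743). DESeq2 called 8 of the adhesion and 10 of the TGF-beta genes, limma-voom 4 and 4. Tgfb1, the ligand itself, fell from 188 ± 46.8 to 102 ± 5.79 CPM (blocked edgeR adjusted p = 0.0785) and was named after its values were seen.

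**Figure D2:**
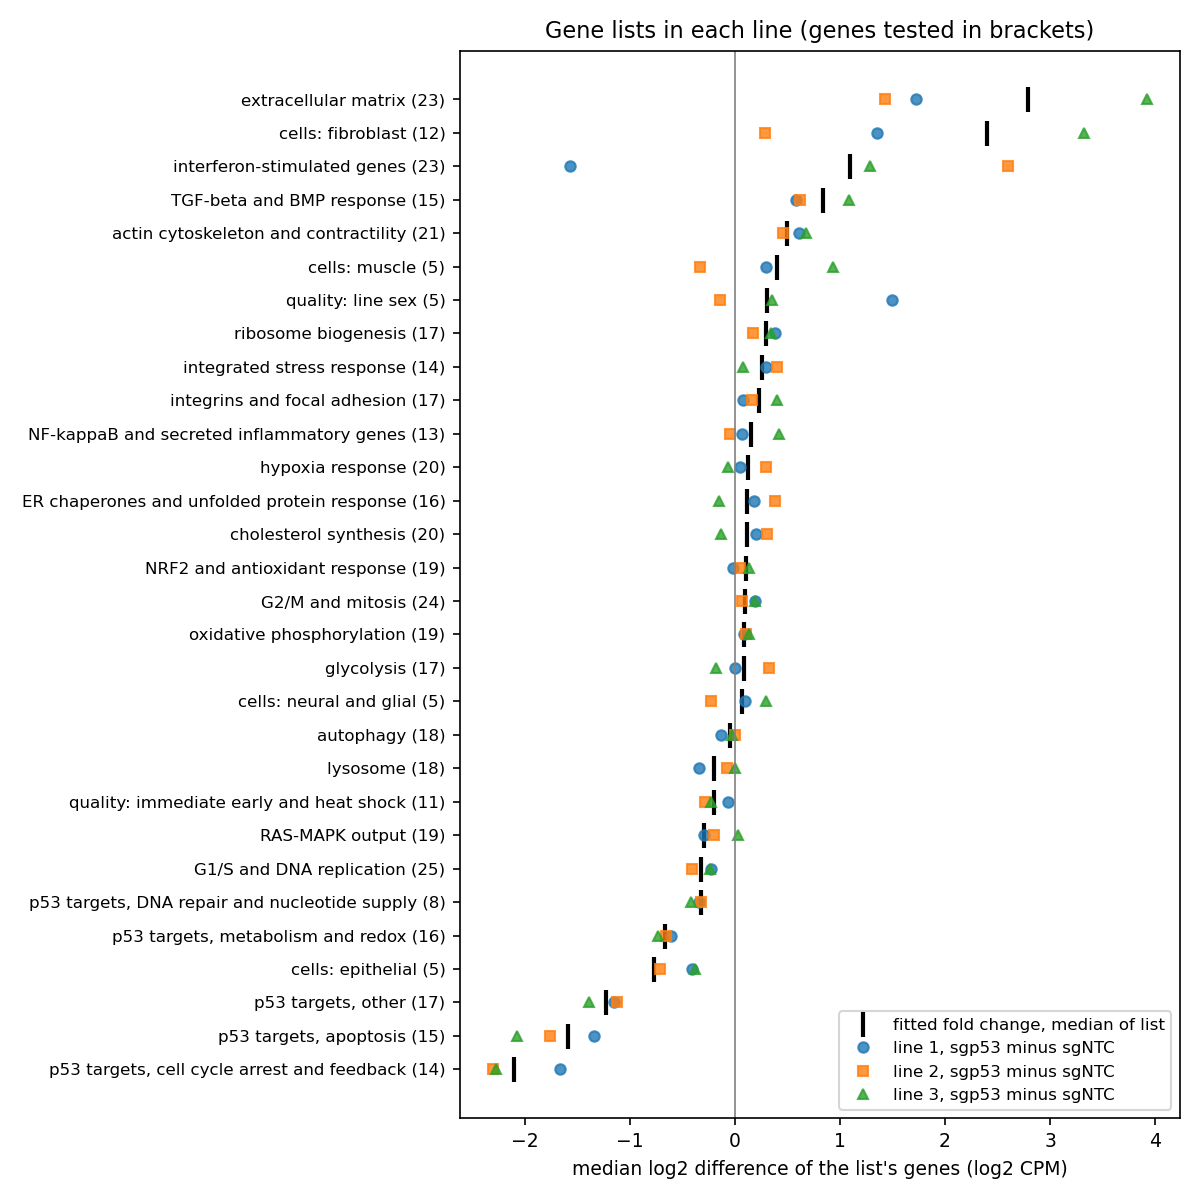
Median log2 difference, sgp53 minus sgNTC, of each gene list within lines 1, 2 and 3 (log2 CPM with a prior count of 2) and the median fitted log2 fold change of the list (black bar), with the number of genes tested in brackets. The lowest fitted median is that of the p53 arrest targets at -2.10, the extracellular matrix list has the highest at 2.79, and the interferon-stimulated genes go from -1.57 in line 1 to 2.60 in line 2.

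Few cell cycle genes passed the test over all genes. Of 25 G1/S and DNA replication genes, 3 were lower and 0 higher (16 lower adjusted over the list alone), with a median log2 fold change of -0.33. These were Pcna, which is also a p53 target of the lists, and the E-type cyclins Ccne2 (58.4 ± 2.32 to 38.5 ± 3.01 CPM) and Ccne1 (95.8 ± 15.6 to 54.3 ± 4.77 CPM, blocked edgeR adjusted p = 0.0626). Its camera call was lost with an estimated correlation (adjusted p = 0.322 with an estimated correlation). Of 24 G2/M and mitosis genes, the checkpoint kinase Bub1b (189 ± 15.9 to 252 ± 12.1 CPM) and the anaphase activator Cdc20 (210 ± 13.5 to 273 ± 23.6 CPM, blocked edgeR adjusted p = 0.0668) were higher (2 adjusted over the list alone). In the blocked fit 1 was higher over all genes and 9 adjusted over the list alone. DESeq2 called 14 of the G1/S genes and 5 of the mitosis genes, limma-voom 3 and 1. The mitosis list passed camera (adjusted p = 0.00264) and missed it with an estimated correlation (0.579). Of 17 ribosome biogenesis genes, 7 were higher (12 adjusted over the list alone, and 1 over all genes in the blocked fit). Among them were Fbl (148 ± 9.55 to 198 ± 13.3 CPM), Pes1 (160 ± 7.29 to 201 ± 11.6 CPM, blocked edgeR adjusted p = 0.0659) and Polr1a (227 ± 7.44 to 293 ± 24.1 CPM, blocked edgeR adjusted p = 0.0676). The list's call was lost (adjusted p = 0.303 with an estimated correlation).

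Targets of Ras-MAPK signalling were more often lower than higher. Of 19 genes, 4 were called lower and Myc was called higher (6 and 1 adjusted over the list alone, and 3 and 0 over all genes in the blocked fit). By sign, 14 log2 fold changes were negative and 5 positive, with a median of -0.295. The list's median difference was -0.296, -0.199 and 0.034 in lines 1, 2 and 3. The list passed camera as down (adjusted p = 0.026) and missed it with an estimated correlation (0.303). The phosphatase Dusp6 fell from 463 ± 55.2 to 279 ± 23.5 CPM, the ephrin receptor Epha2, also in the p53 lists, from 343 ± 5.27 to 253 ± 10.7 CPM, and the immediate early gene Egr1 from 1293 ± 54.8 to 891 ± 68.0 CPM (blocked edgeR adjusted p = 0.0605). DESeq2 called 8 of the 19 genes and limma-voom 5. Myc rose from 32.0 ± 2.98 to 77.6 ± 23.1 CPM (blocked edgeR adjusted p = 0.0655) and was named after its values were seen.

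Metabolic and stress lists had few calls. In the hypoxia response, 2 of 20 genes were higher (5 adjusted over the list alone); the blocked fit had 0 and 3. Vegfa rose from 130 ± 4.64 to 169 ± 9.52 CPM (blocked edgeR adjusted p = 0.0788). The collagen prolyl hydroxylase subunit P4ha2 rose from 45.3 ± 4.08 to 63.4 ± 5.30 CPM (blocked edgeR adjusted p = 0.0787). In oxidative phosphorylation, 2 of 19 were higher (2 adjusted over the list alone); the blocked fit had 0 and 0. The called genes were Cyc1 (207 ± 4.14 to 257 ± 17.0 CPM, blocked edgeR adjusted p = 0.0859) and Sdhb (100.3 ± 4.78 to 125 ± 7.60 CPM, blocked edgeR adjusted p = 0.0724). Both lists passed camera at an adjusted p of 0.0494 and missed it in the blocked fit (0.113 and 0.0834). Their adjusted p was 0.579 and 0.518 with an estimated correlation. In the integrated stress response, Nupr1 was higher (0.961 ± 0.235 to 6.07 ± 4.05 CPM, blocked edgeR adjusted p = 0.0554) among 14 genes (4 adjusted over the list alone); the blocked fit had 0 and 1. The stress list passed camera (adjusted p = 0.00183) and missed it with an estimated correlation (0.303). The autophagy kinase Ulk1 was lower (75.9 ± 3.41 to 59.9 ± 4.27 CPM, blocked edgeR adjusted p = 0.0711) among 18 autophagy genes, and the proton pump subunit Atp6v1a was lower (199.7 ± 9.19 to 153 ± 7.34 CPM, blocked edgeR adjusted p = 0.0783) among 18 lysosome genes. Neither list passed camera (adjusted p = 0.486 and 0.0553). Adjusted over the list alone, 1 autophagy gene was higher and 1 lower, and 3 lysosome genes were lower; in the blocked fit these counts were 0. DESeq2 called 5 hypoxia, 2 oxidative phosphorylation, 4 stress response, 2 autophagy and 6 lysosome genes, and limma-voom 2, 1, 0, 0 and 1.

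EdgeR called 0 genes, over all genes and over the list alone, in the lists of glycolysis, antioxidant response, cholesterol synthesis, ER chaperones and inflammatory genes. Glycolysis (17 genes) had a camera adjusted p of 0.502, with Pkm at 2793 ± 86.4 and 3212 ± 232 CPM and Gapdh at 1855 ± 205 and 2080.1 ± 236 CPM in sgNTC and sgp53. The antioxidant response (19 genes) had 0.566, with Ftl1 at 1175 ± 44.8 and 1372 ± 159 CPM and Prdx1 at 524 ± 31.8 and 509 ± 21.6 CPM. Cholesterol synthesis (20 genes) had 0.0805, with Srebf2 at 269 ± 25.2 and 290 ± 37.5 CPM. The ER chaperones (16 genes) had 0.203, with Hspa5 at 939 ± 107 and 1126 ± 276 CPM and Hsp90b1 at 1033 ± 50.5 and 1161 ± 141 CPM. The NF-kappaB and inflammatory genes (13 genes) had 0.217, with Csf1 at 250 ± 84.5 and 324 ± 82.9 CPM and Nfkb1 at 118 ± 9.81 and 115 ± 6.04 CPM. At an unadjusted p under 0.05 these lists had 1, 3, 2, 2 and 4 genes in the order given, DESeq2 called 1, 2, 2, 1 and 4, and limma-voom called 0 in each.

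Interferon-stimulated genes differed widely between libraries. None of 23 was called by edgeR, over all genes or over the list alone; 1 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. In sgNTC and sgp53, Ifih1, an RNA sensor, was at 162 ± 35.9 and 118 ± 57.5 CPM and Bst2, tetherin, at 67.0 ± 37.0 and 113 ± 130 CPM. The list's median log2 CPM was 4.69, 3.18 and 3.12 in sgNTC lines 1, 2 and 3 and 2.49, 6.02 and 4.81 in sgp53. Its camera adjusted p was 0.0158, with 0.0711 in the blocked fit and an adjusted p of 0.687 with an estimated correlation.

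Markers of cell types were measured to describe the libraries. Of 12 fibroblast markers, 3 were higher in sgp53 and 0 lower (5 adjusted over the list alone). These were Col1a1 and Col1a2, which are also in the matrix list, and the protease Fap (0.109 ± 0.0413 to 0.967 ± 0.579 CPM, blocked edgeR adjusted p = 0.0825). The fibroblast list passed camera (adjusted p = 1.96e-05) and missed it with an estimated correlation (0.329). Krt18, a keratin, fell from 415 ± 199.7 to 66.7 ± 23.8 CPM (blocked edgeR adjusted p = 0.0534). It was the 1 called gene of 5 tested epithelial markers (2 lower adjusted over the list alone). The epithelial list passed camera (adjusted p = 0.0158) and missed it with an estimated correlation (0.222). Cd68, a lysosomal protein of macrophages, fell from 9.23 ± 1.58 to 3.68 ± 0.212 CPM, 1 of 2 tested blood markers (1 adjusted over the list alone), and Map2 fell from 34.1 ± 7.00 to 18.8 ± 2.22 CPM (blocked edgeR adjusted p = 0.0728), 1 of 5 neural markers (1 higher and 1 lower adjusted over the list alone, 0 and 1 in the blocked fit). For the muscle markers (5 tested, 0 called by edgeR, 2 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom; 1 higher and 1 lower adjusted over the list alone, 1 and 0 in the blocked fit) Des was 1.37 ± 0.361 and 0.470 ± 0.172 CPM and Tnnt2 0.741 ± 0.535 and 1.61 ± 0.0527 CPM. The adipocyte markers (2 tested, 0 called by edgeR, DESeq2 or limma-voom, 1 at an unadjusted p under 0.05) Pparg and Cebpa were 5.87 ± 2.15 and 7.16 ± 0.900 CPM in sgNTC and 3.42 ± 0.387 and 8.44 ± 2.33 CPM in sgp53. The endothelial marker Kdr, the 1 tested, was 1.87 ± 0.366 and 1.42 ± 0.0720 CPM. Camera gave an adjusted p of 0.432 for the muscle list and 0.694 for the neural list, whose direction was down while its median log2 fold change was 0.067 and its mean -0.027. Of 11 immediate early and heat shock genes, which can report handling of the cells, Egr1 was lower, with a camera adjusted p of 0.11. Adjusted over the list alone, 1 was higher and 3 lower, against 0 and 1 in the blocked fit, where Egr1 was not called over all genes. DESeq2 called 5 fibroblast, 2 epithelial, 2 neural and 3 immediate early and heat shock genes, and limma-voom 2, 1, 0 and 2. The rotation test fry, which asks whether a list's genes move 1 way on balance, gave the last of these lists an adjusted p of 0.0295, with 0.0183 in the blocked fit.

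The p53 targets were lower in each line, including line 2, whose sgp53 cells are labelled functionally inactive instead of null. The median log2 difference of the 64 targets was -1.17 in line 1, -1.27 in line 2 and -1.29 in line 3, and 60, 59 and 60 of the 64 were lower. Each median lay below those of all 10000 random lists, whose lowest were -0.14, -0.17 and -0.21. Over the 64 targets, the difference was higher in line 1 than in line 2 by a median of 0.18 and than in line 3 by 0.20, and 18 and 15 of them were lower in line 1. It was higher in line 2 than in line 3 by a median of 0.011, and 32 were lower in line 2. Each line had 1 pair, and whether the response differed between lines was not tested.

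Between lines, edgeR called 0 genes in the model with group and line, which has 2 residual degrees of freedom. Of 13044 genes, 461 had an unadjusted p under 0.05, less than the share of 0.05 that chance alone would give. The DESeq2 likelihood ratio test called 79 genes. The 4 genes of smallest p were Rpl29, Esm1, Cdh13 and Col2a1. Rpl29, a ribosomal protein with many near-identical pseudogenes and so uncertain, was 203 and 304 CPM in the sgNTC and sgp53 libraries of line 1 and 61.1 to 69.2 CPM in lines 2 and 3 (edgeR adjusted p = 0.67). Col2a1, a cartilage collagen, was 4.93 and 15.1 CPM in line 1, 2.10 and 7.87 CPM in line 2 and 8.84 and 33.7 CPM in line 3; it was higher in sgp53 in the blocked fit (edgeR adjusted p = 0.0178) and was not called without the block (0.137).

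The sex-linked genes set 1 library apart. In sgNTC line 1 the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 25.2, 16.4, 5.74 and 10.4 CPM, while sgp53 line 1 had 86.8, 43.9, 33.0 and 29.6 CPM. The other libraries had at least 87.4, 51.4, 25.9 and 34.6 CPM. Xist, the RNA that silences an X chromosome, was 3.64 CPM in sgNTC line 1 and 0.508 to 0.717 CPM in the other 5 libraries. None of these 5 genes was called between sgp53 and sgNTC by edgeR, over all genes or over the list alone. Of the 5, 0 had an unadjusted p under 0.05, DESeq2 and limma-voom called 0, and their list had a camera adjusted p of 0.477.

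**Figure D3:**
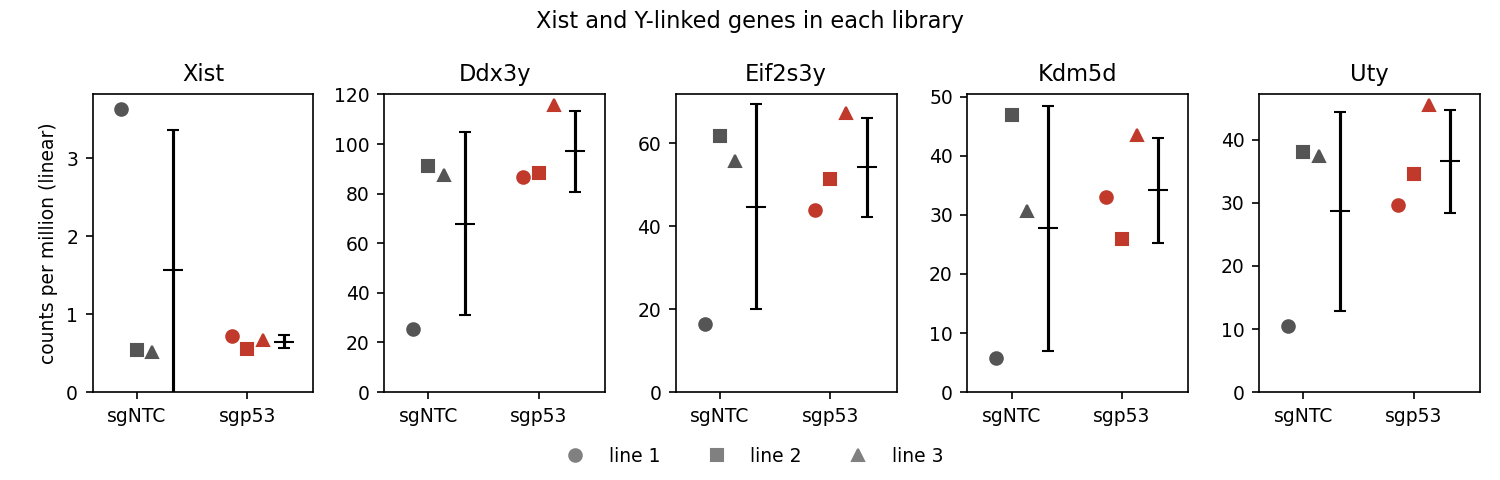
CPM (linear axes) of Xist and 4 Y-linked genes in each library, with circles, squares and triangles for lines 1, 2 and 3, and the mean with SD as a bar beside each group of 3 (the lower end of the Xist bar is cut at 0). Xist is 3.64 CPM in sgNTC line 1, above the other 5 libraries, and the Y-linked genes are lowest there.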

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

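Of the tests in this part, those of female cells and of loss of the Y chromosome in sgNTC line 1, that of the swap on all p53 targets, and that of the matrix list against random lists were chosen only after the result was seen. Single outlying libraries were not tested, since the smallest group for such a test was set at 4 and the groups here had 3.

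The interferon-stimulated genes moved in opposite directions between the lines: the list's median log2 difference, sgp53 minus sgNTC, was -1.57 in line 1, 2.60 in line 2 and 1.29 in line 3. Bst2, of the same list, had differences of -1.85, 2.75 and -0.20 in lines 1, 2 and 3. For Kdm5d, on the Y chromosome, they were 2.51, -0.85 and 0.51. Each line had 1 pair, and none of these differences was tested.

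The low Y-linked RNA of sgNTC line 1 stood beside more Xist. Swapped sgNTC and sgp53 libraries are argued against by the 64 tested p53 targets. Over these, sgNTC line 1 lay above the sgp53 libraries by a median of 1.25 (log2). Of the targets, 60 were nearer to the other sgNTC libraries, against 4 in sgp53 line 1. That comparison checks the group label only, since a swap within line 1 would still leave 1 library with low Y-linked RNA. Loss of the Y chromosome in a share of the cells does not account for the whole pattern, since Xist was higher than in the other sgNTC libraries by 2.65. Female cells mixed into the library stay open: X-linked genes that escape silencing (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) were higher by a median of 0.082, between the 0 set as the bound against and the 0.2 set as the bound for. No other biological explanation was tested.

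For the rise of extracellular matrix genes, whose list call was lost with an estimated correlation (adjusted p = 0.132 with an estimated correlation), scaling of the libraries is argued against. A scaling difference moves all genes of a library alike, and the list's median lay 2.55 above the highest of 10000 random lists matched on mean expression; the test first set, with upper quartile factors (median 2.79), could not decide, since they shift all genes alike. A rise in 1 line alone is argued against by the lowest median of 1.54, when line 3 was left out, above the bound of 0.5 and with 22 of 23 genes above 0. Lower output of E1A in the sgp53 cells stays open: the E2F-driven G1/S and DNA replication list had a median of -0.33, between the bounds of -0.5 and -0.1, and E1A itself was not measured here. The difference in p53 state that the design names may account for the rise and also stays open, since each sgp53 library would share both.

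High Rn45s in sgp53 line 3 may come from more RNA without a poly(A) tail in that library, and the test left this open. The 20 other RNAs taken as such included 18 histone genes picked by name. The median log2 difference of the 20 from the other sgp53 libraries was -0.20, below the bound of 0.2 set beforehand against the explanation. Their spread (median absolute deviation 0.67) reached past that bound, and 9 were higher and 11 lower. That this spread should count was settled after the median was seen. Whether each histone transcript lacked a poly(A) tail was not measured, so the histone values cannot decide. The 18 histone genes had a median of -0.22, and the 3 of highest level, Hist1h1c, Hist3h2a and Hist1h2bc, had -0.44, -0.58 and -0.62. Rmrp and Rpph1 were higher by 2.49 and 2.09, beside 2.32 for Rn45s, but were at most 0.717 CPM in the other sgp53 libraries, as were 9 of the 18 histone genes. No biological explanation was tested.

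For the real split of the 6 libraries, edgeR called 841 genes and 45 p53 targets, and 1 of the 10 splits, the real one, gave as many in each case; the highest of the other splits had 0 and 0. Camera called 19 lists in the real split, and 1 of the 10 splits gave as many, with 18 as the highest of the others. The 3 other splits that part all 3 lines called 0 genes and at most 12 lists. With 10 splits the share cannot go under 0.05. Each other split puts sgNTC and sgp53 libraries together on both sides, so the group difference widens the spread within its sides. Their 0 gene calls therefore do not measure what would be called without a group difference. The other splits called 10 to 18 lists and can carry part of that difference.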

How the results depend on the processing

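Of the results here, those without Rn45s and without both sgNTC line 1 and sgp53 line 3 were chosen after seeing the data. The counts of genes higher in sgp53 (360), genes lower in sgp53 (481) and p53 target genes lower in sgp53 (45) stayed within 1.5 times under RLE and upper quartile factors, both filters, limma-voom and without Rn45s. DESeq2 gave 1190 higher and 1192 lower, DESeq2 with the replicate block 867 and 807, the edgeR replicate block 126 and 185, and the fit without sgNTC line 1 and sgp53 line 3 164 and 272. In the replicate block with line 2 left out, which has 4 libraries, 0 genes were higher, 0 lower and 0 p53 targets lower, and Trp53 was -1.34 (edgeR adjusted p = 0.0955, against 1.68e-18 to 0.112 over its alternatives). With 1 library or line left out, 4 to 251 genes were higher, 15 to 449 lower and 10 to 40 p53 targets lower, Trp53 ranged from -1.78 to -1.31, the called lists from 14 to 21, and the genes between lines stayed at 0. Fewer libraries leave fewer degrees of freedom; what else lowered these counts was not tested. Camera with an estimated correlation called 3 lists instead of 19. In camera this setting also lowers the degrees of freedom of the test, so the lost calls cannot be put down to the size of the estimates alone. The p53 metabolism and redox list, with an estimate of 0.029, went from a camera adjusted p of 2.79e-13 to 0.0445. Against the preset of 0.01, the estimates of the 19 lists ran from 0.029 (p53 metabolism and redox targets) to 0.875 (interferon-stimulated genes). The DESeq2 likelihood ratio test called 79 genes between lines instead of 0, and the cause of that was not tested. Fry called 16 lists: it kept 14 of the 19, lost mitosis, hypoxia, oxidative phosphorylation, interferon-stimulated genes and fibroblast markers, and added muscle markers (adjusted p = 0.0473) and immediate early and heat shock genes (0.0295). The p53 target medians per line moved by less than the spread between lines under all 3 alternatives. Of 63 called named genes, 28 to 48 kept the call with 1 library left out, 12 to 20 with a line left out, 45 in the replicate block and 63 in DESeq2, and none changed sign. In edgeR and camera the block changed no call of a named gene or list other than those given beside the results. In fry the block removed the calls of G1/S and DNA replication (adjusted p = 0.0604), integrins and focal adhesion (0.12), integrated stress response (0.103) and muscle markers (0.0931). The fry calls of Ras-MAPK output and ribosome biogenesis were also lost with the block (0.0904 each). Sign changes were among genes that were not called: in the replicate block with line 2 left out Prdx1 was 0.0085 and Bst2 -1.02; without sgNTC line 1 and sgp53 line 3 Ddx3y was -0.025, Eif2s3y -0.30, Xist 0.27, Kdm5d -0.40 and Uty -0.23. With 1 library or line left out the ranges were -0.086 to 0.0092 for Prdx1, -1.08 to 1.75 for Bst2, -0.046 to 0.81 for Csf1, -0.097 to 0.020 for Nfkb1, -0.0026 to 0.40 for Cebpa, 0.12 to 0.86 for Ddx3y, -0.12 to 0.64 for Eif2s3y, -0.70 to 1.24 for Rpl29, -1.72 to 0.29 for Xist, -0.18 to 1.09 for Kdm5d and -0.045 to 0.67 for Uty. Camera directions changed for glycolysis (adjusted p 0.0516 to 0.816), the antioxidant response (0.233 to 0.9499), the neural markers (0.707 to 0.977) and the interferon-stimulated genes (8.49e-17 to 0.956). The cause of these sign changes was not tested. At this depth genes of a few counts, such as Robo3 and Igfbp5, give wide ratios.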

Other observations

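The hypothesis that a library carries a gained or lost chromosome in most of its cells was tested on the median log2 deviation of each chromosome from the other libraries of the group, over 20 chromosomes with at least 50 tested genes, which leaves out the Y chromosome. The largest deviation was -0.26, on chromosome 14 in sgNTC line 2, followed by 0.24 on chromosome 19 and -0.23 on chromosome 1 in sgNTC line 1. These 3 of 120 values lay beyond 0.2 and 0 lay beyond 0.4, so the test did not decide between the bounds set before the data were examined. A chromosome change in part of the cells may remain.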
